A study of Caenorhabditis elegans with 3 samples.

How the data were processed

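The series holds 3 small RNA libraries from whole mixed-stage Caenorhabditis elegans grown at 20 °C, 1 from dcr-1(ok247) animals with an array of normal Dicer and 2 from animals with an array of Dicer K39A. Per the labels' protocols, Trizol RNA went through an Illumina small RNA protocol that depends on ligation to the 5' end, and small RNAs were cut from a gel. The deposited files list alignments made with Novoalign, per the submitters' processing notes, and the file names give the build as ce6. The version and settings of Novoalign and the adapter trimming are not given in the sources used here. The deposited values are an alignment score per hit, a quality score per read, a further score of unstated meaning and the position of each hit, none of them normalized. The alignment score served only to describe read quality and to pick clean matches for placing miRNAs.

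Reads were counted from the lines of each file, with 1 line per read and hit. The files held 3582492 reads in WT, 5231154 in K39A replicate 1 and 3448376 in K39A replicate 2, each 18 to 36 nt long, with 0.191%, 0.144% and 0.0912% matching the added adapter sequence. Of the genome-matched reads 93.7%, 95.4% and 95.7% had 1 match, and 7.78%, 10.5% and 11.6% listed a mismatch. A read with several matches, up to 9 listed, was split equally over them. The size factor of each library was its number of genome-matched reads outside ribosomal DNA: 3346615 in WT, 5076949 in K39A replicate 1 and 3354494 in K39A replicate 2. RPM stands for reads scaled by this factor. Fragments of tRNA, snRNA and snoRNA were to be left out of it as well, which needs gene models for ce6. At this depth a count of 0 allows up to 3 reads, which is 0.896, 0.591 and 0.894 RPM. Shares of single libraries carry 95% exact Clopper-Pearson intervals, and ratios of reads carry exact conditional binomial intervals.

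The annotation at hand belongs to another genome build than ce6, and no coordinates were moved between builds. miRNAs were placed on ce6 through 116 mature sequences written down from general knowledge, each matched to read sequences. The reads held 109 of them, all 109 on the annotated chromosome and strand and in the annotated order, and 7 were not seen. mir-44 and mir-45, with 1 mature sequence, were merged. Reads whose 5' end lay within 3 nt of a mature 5' end were counted for that miRNA, reads 30 to 60 nt away for the other arm, and reads within 110 nt for the miRNA class. The arm of a miRNA was read from the side with more reads of the other arm. The remaining classes were the ribosomal DNA end of chromosome I, 21-nt reads beginning with U on chromosome IV (21U), 26-nt reads beginning with G (26G), reads of 21 to 23 nt beginning with G (22G) and other reads. Without gene models for ce6, siRNAs could not be assigned to genes. In their place 26G-type reads on 1 strand were joined into loci over gaps of up to 1000 nt, 22G-type reads over gaps of up to 500 nt, and all reads outside the miRNA, ribosomal and 21U classes were counted in windows of 2 kb, both strands together. Of the 18 lists fixed before the data were examined, 10 miRNA lists were tested. The 8 lists of protein-coding or structural RNA genes and the reads at dcr-1 itself were not analysed here, for the same reason.

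Features with at least 20 reads over the 3 libraries were tested with limma 3.58.1 in R 4.3.3, with voom weights on log2 RPM, moderation over all features of a class and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The lone WT library was assumed to vary like the K39A pair, which leaves 1 residual degree of freedom. Before the fit the K39A pair was checked against sampling noise, and it differed by more in every class. The lists were tested with camera, with a preset correlation of 0.01 and with an estimated one. Ends and arms of miRNAs used miRNAs with at least 200 reads in each library. Counting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

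The fits were tested on simulated data. The spread between libraries was a median-based one of the K39A pair, over features with at least 100 reads and beyond counting noise. It varied between features as in the real fit, up to a cap. For miRNAs it was 0.583 per library on the log2 scale, while the SD of the pair's log2 ratio over all 99 was 1.20. A median-based spread gives little weight to features that differ widely, so the real share of calls may be lower. Of features set 4-fold, 16-fold and 64-fold lower, the fit called 2 of 10, 10 of 10 and 10 of 10 miRNAs, 21 of 56, 64 of 67 and 66 of 66 positions of 21U, 12 of 17, 19 of 19 and 20 of 20 loci of 22G, and 10 of 55, 40 of 62 and 62 of 65 windows. Of features set equal it called 0 of 69 miRNAs, 10 of 3370 positions of 21U, 3 of 277 loci of 22G and 18 of 2655 windows. The 11 loci of 26G-type reads were too few to simulate.

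Named features followed a rule fixed before the data were examined. It took up to 10 features with the largest fall and up to 10 with the largest rise among those that passed the test, with a mean of at least 10 RPM (50 for miRNAs) and both K39A libraries on the same side of WT. It also took the 10 most abundant features of each class and the most abundant members of the lists. Any feature named outside the rule is said to have been chosen after its values were seen.

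Alternatives fixed before the data were examined were size factors from miRNA reads, from a TMM-type trimmed mean and from the median of ratios, single-match reads only, minimums of 1 and 100 reads, limma-trend on log2 RPM plus 1 for miRNAs, 26G loci and windows, other denominators and length rules of the classes, a minimum of 1000 reads for ends, and each K39A library left out. Alternatives added after the data were seen were reads with no listed mismatch, miRNA reads of 21 to 23 nt, 26G loci from reads of 25 to 27 nt, 22G loci from reads of exactly 22 nt, the loci and windows themselves, and the set of windows that hold a 26G locus.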

Results

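Small RNA was sequenced from whole Caenorhabditis elegans of mixed stages that lacked their own Dicer, the RNase III enzyme that cuts miRNA and siRNA precursors. All animals carried the dcr-1(ok247) allele and an array that supplied Dicer again. The array held normal Dicer in 1 library, named WT here, and Dicer with the K39A change in its helicase domain in 2 libraries, named K39A replicates 1 and 2. The worms had grown at 20 °C. WT held 3575667 reads that matched the ce6 genome, K39A replicate 1 held 5223614 and K39A replicate 2 held 3445230. Nothing in the labels says that the K39A libraries came from separate cultures, so every p value measures only the spread between these samples. The comparison asked which small RNAs need an intact Dicer helicase domain.

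The libraries differed in read length and read quality as well as in genotype. Reads of 18 to 20 nt made up 11.5% of WT, 6.06% of K39A replicate 1 and 3.95% of replicate 2. Reads of 24 nt or more made up 0.773%, 2.07% and 1.89% in the same order. An alignment score of 0, given to clean matches, was held by 87.2% of WT reads, 75.5% of K39A replicate 1 reads and 37.5% of replicate 2 reads. The K39A pair also differed from each other by more than sampling noise, with a chi-square per degree of freedom of 3979 over miRNAs and 16.6 over 21U-RNAs.

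Among the read classes, miRNAs took a larger share in both K39A libraries, while ribosomal fragments, 21U-RNAs and 26G-type reads took smaller shares. The miRNA share was 77.6% in WT and 85.8% ± 0.447 (SD, n = 2) in K39A. Fragments from the ribosomal DNA end of chromosome I took 6.41% in WT and 2.72% ± 0.123 in K39A, a log2 ratio of -1.24. Reads like 21U-RNAs, the germline piRNAs of worms, took 11.5% in WT and 8.69% ± 0.393 in K39A, a log2 ratio of -0.41. Each of these 3 differences exceeded the K39A pair's own log2 gap, which was 0.011 for miRNAs and 0.092 for ribosomal fragments and 21U-RNAs. The difference of 26G-type reads did not, with a log2 ratio of -1.99 against a gap of 2.36, although both K39A libraries lay under WT (-1.25 and -3.61). Other reads had a log2 ratio of -0.76 against a gap of 0.056. Reads like 22G-RNAs, the siRNAs made by RNA-dependent RNA polymerases, took 0.572% in WT (95% exact interval 0.564 to 0.580), 0.416% in K39A replicate 1 and 0.585% in replicate 2. The 22G shares of the K39A pair lay on both sides of WT with all genome-matched reads as the denominator, and both below WT against reads outside ribosomal DNA (0.611% in WT, 0.428% and 0.600% in K39A) and against miRNA reads. Intervals cover counting error only, since reads copied from the same molecule cannot be told from separate molecules. The library method joins adapters to 5' monophosphates, so 22G-RNAs, which carry triphosphates, would be caught poorly, which was not measured here.

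**Figure D1:**
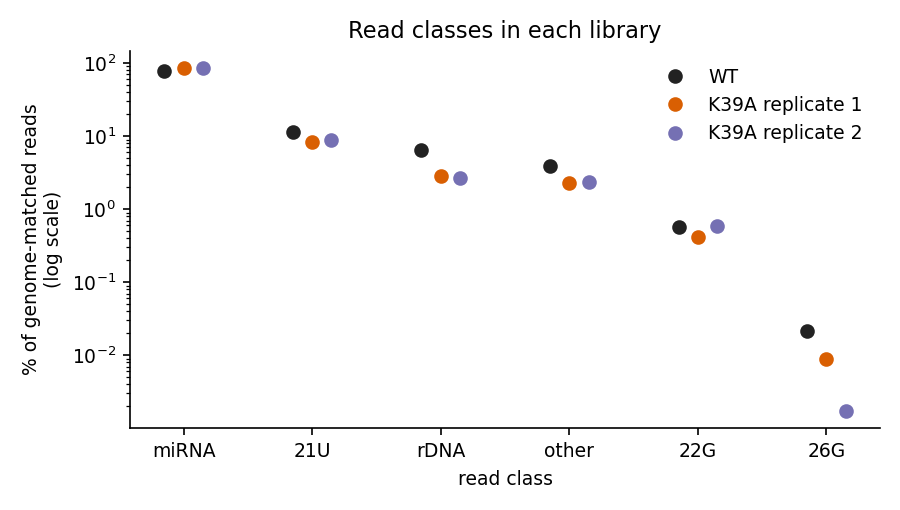
Share of genome-matched reads (%, log scale) in each of 6 read classes, with 1 point per library. The 26G class shows the widest gap on this scale, from 0.0212% in WT to 0.00174% in K39A replicate 2.

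Reads of 26 nt that begin with G, the form of the primary siRNAs called 26G-RNAs, were scarcer in both K39A libraries, counted outside miRNA hairpins and ribosomal DNA. They made up 0.0212% of WT reads (95% exact interval 0.0197 to 0.0228), 0.00891% of K39A replicate 1 (0.00811 to 0.00975) and 0.00174% of K39A replicate 2 (0.00133 to 0.00224). G was the first base of 94.6% of 26-nt reads outside these classes in WT, of 35.8% in K39A replicate 1 and of 32.3% in K39A replicate 2. With no-mismatch reads alone the shares were 0.0192%, 0.00526% and 0.000624% in the same order, a wider gap. Under the wider rule of 25 to 27 nt with G as first base, the shares were 0.0319% in WT, 0.0357% in K39A replicate 1 and 0.0123% in K39A replicate 2, so replicate 1 was then higher than WT. Reads of 26 nt with another first base, outside the same classes, went the other way, from 0.00122% in WT to 0.0160% and 0.00364% in K39A.

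**Figure D2:**
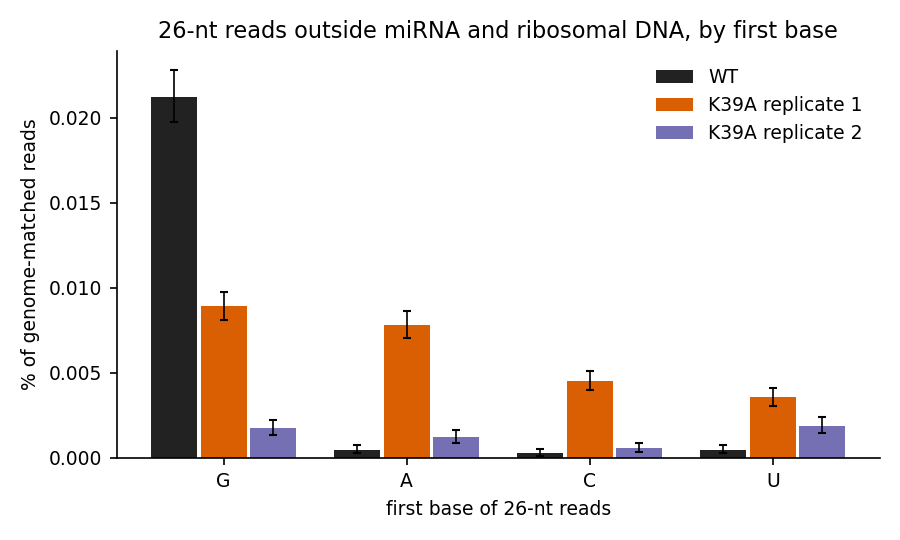
26-nt reads outside miRNA hairpins and ribosomal DNA by first base, as % of genome-matched reads, with 1 bar per library and 95% exact binomial intervals. G stands out in WT alone, at 0.0212%, and is 0.00891% and 0.00174% in the K39A libraries.

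The 26G-type reads gathered at 11 loci with at least 20 such reads over the 3 libraries, which held 483 of the 759 WT reads. Outside the 11 loci such reads stood at 82.6 RPM (reads scaled to a common library size) in WT, 70.8 in K39A replicate 1 and 12.8 in K39A replicate 2, so replicate 1 was little lower there. All 11 loci together held 106 reads in K39A replicate 1 and 17 in K39A replicate 2, which is 0.145 (95% exact interval 0.116 to 0.179) and 0.0351 (0.0203 to 0.0568) of the WT level. Every locus but that at 12890277 of chromosome X reached 20 reads in WT alone. The choice of loci thus favours low K39A levels in all ratios and medians over them. The shares of the whole class given above do not have this limit. At 9 of the 11 loci both K39A libraries lay more than 4-fold under WT. These 9 loci together held 364 reads in WT, 17 in K39A replicate 1 and 0 in K39A replicate 2. K39A replicate 1 thus held 0.0308 of the WT level in RPM (95% exact interval 0.0177 to 0.04998), and K39A replicate 2 was at least 122-fold lower than WT, against a floor of 3 reads per library. The 9 loci were set apart after their values were seen, and the median over all 11 was 23.5-fold lower in the K39A pair, with loci at 0 set to the floor. The fitted median log2 was -5.13 over the 11 loci and -0.50 over the 28 loci built from reads of 25 to 27 nt. With a minimum of 1 read it was 0.092 over 317 loci. The TMM-type scaling gave -1.66 over the 11 loci, with 0.23 and -6.23 in the K39A replicates 1 and 2. It left replicate 2 unscaled against WT, since no locus had 26G-type reads in both. The annotation at hand is for another genome build, so genes at these loci are not named.

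The locus on chromosome V from 17073349 to 17073892, minus strand, held 88 such reads in WT, 2 in K39A replicate 1 and 0 in replicate 2. On chromosome II from 13477744 to 13479212, minus strand, the counts were 52, 2 and 0 in the same order. A plus-strand locus on chromosome II from 2681454 to 2681634 held 48, 2 and 0. On chromosome V from 20379611 to 20379711, minus strand, there were 43, 1 and 0. A plus-strand locus on chromosome II from 2136681 to 2136888 held 37, 3 and 0. The other 4 lay on the minus strand: chromosome V from 20376119 to 20377394 with 28, 3 and 0, chromosome X from 17253972 to 17254226 with 24, 1 and 0, chromosome III from 2427269 to 2429335 with 22.7, 0 and 0, and chromosome V from 17069130 to 17069824 with 21, 3 and 0.

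Both remaining loci behaved otherwise. On chromosome II from 3291529 to 3291778, minus strand, 26G-type reads stood at 35.6 RPM in WT, 10.8 in K39A replicate 1 and 0 in replicate 2, where the floor of 3 reads leaves it at least 39.8-fold lower than WT. At 1 start there, position 3291754, 26-nt reads numbered 100, 45 and 0. From position 3291753, the next base downstream, 24-nt reads numbered 6, 77 and 73. On chromosome X at position 12890277, minus strand, 26G-type reads were seen only in K39A, with 34 and 17 reads. This locus stayed at least 2-fold higher in both K39A libraries with single-match reads only. With no-mismatch reads only it fell below the read minimum, so most of its 26G-type reads listed a mismatch.

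The test of these 11 loci depended on the method. limma with voom weights called 0 of 11 loci, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.840. limma-trend on log2 RPM plus 1 called 9 loci, all lower in K39A, with a smallest adjusted p of 0.000649. In both, the lone WT library is assumed to vary like the K39A pair, which leaves 1 residual degree of freedom. At the 9 loci set apart above, neither K39A library exceeded 0.591 RPM. Adding 1 RPM draws such low values together, so the spread of the K39A pair under limma-trend is small there by construction.

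**Figure D3:**
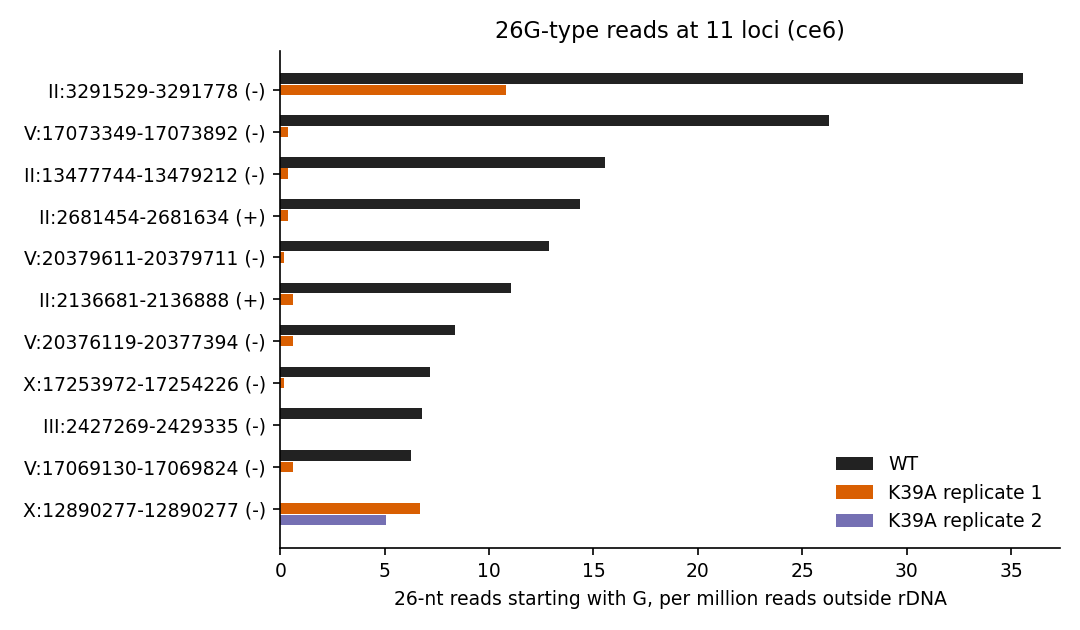
Reads of 26 nt that begin with G at each of the 11 loci, in RPM, with 1 bar per library. At 9 loci the WT bar stands alone or nearly so. The locus on chromosome II from 3291529 to 3291778 keeps 10.8 RPM in K39A replicate 1, and the locus on chromosome X at 12890277 has reads in K39A alone.

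Other small RNA at the 9 loci, which were set apart by their 26G-type reads, was lower as well. Within these loci and 500 nt on each side, 22G-type reads on the same strand numbered 264 in WT, 68.5 in K39A replicate 1 and 83.3 in K39A replicate 2, which is 0.170 (95% exact interval 0.128 to 0.222) and 0.314 (0.242 to 0.403) of the WT level in RPM. Over all 11 loci the 22G levels were 0.480 (0.410 to 0.563) and 0.690 (0.587 to 0.810) of WT, since both other loci held more 22G-type reads in K39A. The locus on chromosome V from 17073349 to 17073892 kept most of them, with 59, 49 and 58.5 reads. Reads on the opposite strand numbered 456 in WT, 7 in K39A replicate 1 and 3.67 in replicate 2. Their level in K39A was 0.0101 (0.00405 to 0.0210) and 0.00875 (0.00237 to 0.0226) of WT, and over all 11 loci 0.0378 (0.0250 to 0.0549) and 0.0256 (0.0136 to 0.0442).

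The genome was also counted in 2-kb windows outside miRNA, 21U and ribosomal sites, both strands together. Of the 13 tested windows that hold a 26G locus, 12 were lower in both K39A libraries after 26G-type reads were left out, with a median log2 of -4.30 against -0.85 over all 3096 windows. They held 1543 reads in WT, 689 in K39A replicate 1 and 479 in replicate 2. camera, limma's set test, gave p = 4.04e-05 with a preset correlation and p = 0.267 with an estimated correlation. This set was chosen after the data were seen, and under the TMM-type scaling the median moved to -3.46 and that over all windows to 0.0199.

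Across all 3101 windows limma with voom weights called 0, with 531 at an unadjusted p under 0.05, of which 522 were lower in K39A, and limma-trend also called 0, with 408 at an unadjusted p under 0.05. That balance depends on the scaling, since the TMM-type scaling gave 64 lower and 42 higher at an unadjusted p under 0.05 and the median of ratios 63 and 40. Of the 10 windows richest in reads, 6 were lower and 3 higher in both K39A libraries in RPM. Chromosome V from 5780001 to 5782000 was among the lower, at 1504 RPM in WT and 450 ± 61.6 (SD, n = 2) in K39A. Chromosome IV from 1026001 to 1028000 was among the higher, at 166 in WT and 593 ± 128 in K39A. Neither passed the test with the minimum of 20 reads over all matches, and both passed it with single-match reads, with no-mismatch reads and with a minimum of 1 read. With single-match reads 33 windows were called, 32 of them lower and 5 of those called holding a 26G locus. The median over windows was -0.85, and -0.94 with the miRNA size factor. It was 0.021 under the TMM-type scaling, which sets the typical window level by construction.

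At 22G-type loci, limma with voom weights called 2 of 376, and both fell in K39A. The locus on chromosome X from 9071753 to 9073222, minus strand, fell by 7.79 on the log2 scale (SE 1.58, limma adjusted p = 0.000476). It held 155 such reads in WT, 1 in K39A replicate 1 and 0 in replicate 2. In WT its reads of 18 nt (256) and 19 nt (217) outnumbered those of 21 nt (109), 22 nt (64.9) and 23 nt (15.5). Random fragments stay open for this locus, with values on both sides, as weighed further below. The locus on chromosome II from 2681448 to 2681530, plus strand, fell by 6.33 (SE 1.501, limma adjusted p = 0.00581) and held 56, 0 and 1 reads; it overlaps the 26G locus from 2681454 to 2681634. At an unadjusted p under 0.05 there were 24 loci, all lower in K39A. A minimum of 100 reads, reads with no listed mismatch or reads of exactly 22 nt each left 0 calls, with 10, 9 and 5 loci at an unadjusted p under 0.05.

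None of the 10 loci richest in 22G-type reads passed the test with limma. The locus with the most reads, at position 11782969 of chromosome V, plus strand, held 87.9 RPM in WT and 85.8 ± 3.72 (SD, n = 2) in K39A. On chromosome IV from 7256478 to 7256587, minus strand, WT held 25.5, K39A replicate 1 held 23.1 and replicate 2 held 130. The 22G reads around the exceptional 26G locus, on chromosome II from 3291447 to 3291793, were 22.1 in WT and 33.6 ± 7.70 in K39A.

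No miRNA passed the test for a difference between WT and K39A. Bantam-related mir-58, on chromosome IV from 3233310 to 3233331, held 400695 RPM in WT and 388182 ± 22374 (SD, n = 2) in K39A. The let-7 relative mir-48, on chromosome V from 14364450 to 14364472, held 105416 in WT and 127092 ± 25358 in K39A. Muscle mir-1, on chromosome I from 6172679 to 6172699, held 89108 in WT and 76547 ± 7554 in K39A. For mir-71, on chromosome I from 9379974 to 9379996, the values were 77978 and 81299 ± 17894. The timing miRNA let-7, on chromosome X from 14744155 to 14744176, held 18256 in WT and 28459 ± 7734 in K39A, a log2 difference of 0.59 (SE 0.62). K39A replicate 2 stood apart at mir-70, with 109688 RPM against 20041 in WT and 20003 in K39A replicate 1.

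Of the others among the 10 most abundant, mir-44 and mir-45, which share 1 mature sequence, held 34066 in WT and 24223 ± 4784 in K39A. mir-81 held 16416 and 12401 ± 1050. mir-72 held 8527 and 16673 ± 2904, and mir-34 held 6847 and 13143 ± 4112. limma with voom weights called 0 of 99 miRNAs, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.722, and limma-trend called 0 with 7. In both K39A libraries 2 miRNAs were at least 2-fold lower than WT and 11 at least 2-fold higher. Simulated counts, with WT given the median-based spread of the K39A pair, gave calls for 20% of 10 miRNAs set 4-fold lower and 100% of 10 set 16-fold lower. Differences near 4-fold would thus mostly be missed at this depth and number of libraries.

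**Figure D4:**
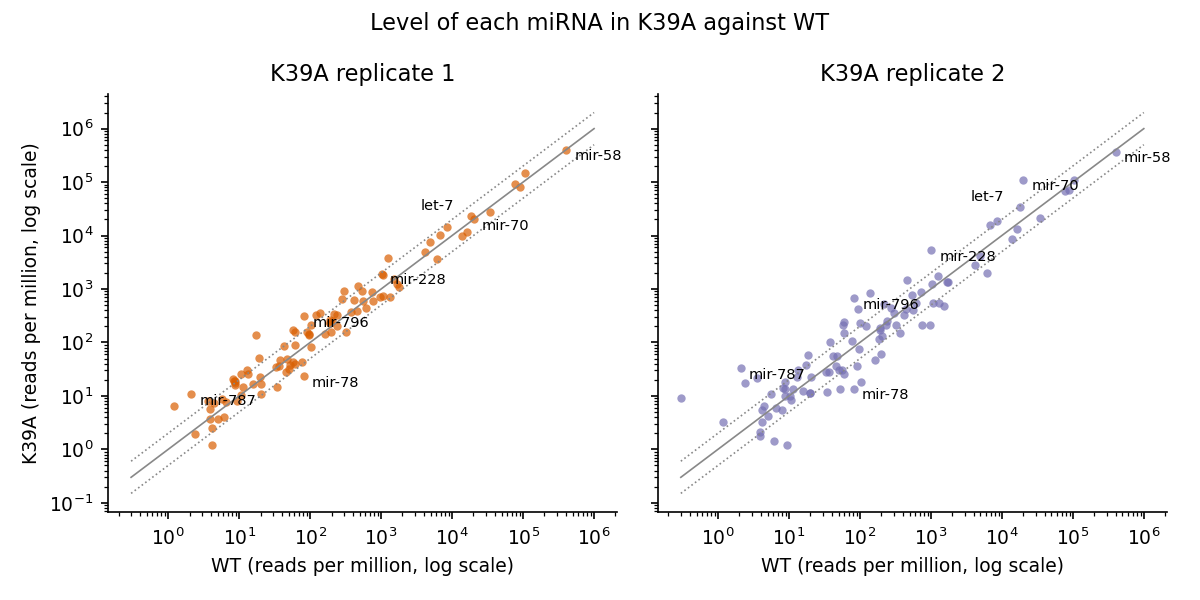
RPM of each miRNA in WT (x axis, log scale) and in each K39A library (y axis, log scale). The full line marks equal levels and the dotted lines a 2-fold difference. mir-58 lies on the line in both panels, and mir-70 leaves it in K39A replicate 2 alone, at 109688.

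Single miRNAs chosen after their values were seen show some of the larger differences, and none passed the test with a minimum of 20 reads. mir-796 held 82.8 RPM in WT, 308 in K39A replicate 1 and 670 in K39A replicate 2 (limma adjusted p = 0.722). mir-78 held 81.3, 23.2 and 13.7 in the same order. The glial mir-228 held 1019, 1944 and 5303. mir-229 (17.3, 139.9 and 38.5) and mir-248 (138.05, 355 and 831) had larger log2 differences than mir-228, as did mir-60 and mir-67. mir-787 held 7 reads in WT, 54 in K39A replicate 1 and 110 in K39A replicate 2, and was the only call with a minimum of 100 reads (limma adjusted p = 0.00443). Under the other settings with a test, the smallest limma adjusted p of any miRNA ranged from 0.200 to 0.926.

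None of the 10 miRNA lists fixed before the data were examined was called by camera, with a preset or an estimated correlation. Adjusted over the list alone, limma with voom weights called 0 members of each list, and over all miRNAs 0 as well, while limma-trend called 1 member of the mir-64 family when adjusted over that list alone. The lin-4 family of developmental timing miRNAs had a median log2 of -0.72 (2 of 2 members lower in both K39A libraries), and the mir-44 family a median of -0.80 (2 of 2). The mir-35 family, made in oocytes and embryos, had a median of -0.34 over 7 members, 4 of them lower in both. In mir-35 itself WT held 1764 RPM and K39A held 1205 ± 176 (SD, n = 2). The bantam-related mir-58 family had a median of -0.23 over 4 members. Medians stayed negative for these 4 lists under all 4 scalings.

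The let-7 family had a median of 0.27 over 7 members, with mir-84 at 1.46 and mir-241 at -1.17. The mir-51 family had 0.38 over 6, the mir-64 family 0.54 over 5 and the mir-72 family 0.30 over 3. Medians of these 4 lists stayed positive under all 4 scalings, and that of the mir-51 family was -0.09 with reads of 21 to 23 nt only. The mirtrons, made by splicing in place of Drosha, had 0.51 over 3 members, against 0.077 with the TMM-type scaling and 0.019 with the median of ratios, and the K39A replicates 1 and 2 parted at -0.071 and 2.57. The muscle, neuron and glia list had a median of -0.18 but a mean of 0.18 over 5 members, from -1.26 for mir-124 to 1.63 for mir-228. Over the 10 lists the smallest camera adjusted p was 0.461 with a preset correlation and 0.973 with an estimated correlation.

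miRNA ends, of which Dicer cuts 1 on each arm, were alike at the 5' side, while the 3' side was more uniform in K39A for most miRNAs but less so for some of the most abundant. Over 52 miRNAs with at least 200 reads in each library, the commonest 5' end took a median of 98.7% of reads in WT, 98.8% in K39A replicate 1 and 99.2% in replicate 2. The median change was 0.23 points (0.079 and 0.396 in the K39A replicates 1 and 2), and 0 miRNAs moved by 10 points in both K39A libraries. For the 26 miRNAs read as lying on the 3' arm, whose 5' end Dicer makes, the median change was 0.068 points. The commonest 3' end took 83.4%, 86.6% and 87.0%, a median change of 2.28 points (1.14 and 3.45 in the K39A replicates 1 and 2). That share was higher in both K39A libraries at 38 miRNAs and lower in both at 8. At 8 miRNAs it was at least 10 points higher in both K39A libraries, and at 0 it was 10 points lower. For the 22 miRNAs read as lying on the 5' arm, whose 3' end Dicer makes, the median change was 2.29 points, with 5 at least 10 points higher in both. For the 3' ends of the 26 on the 3' arm it was 1.82 points, with 2. Some arm calls rest on few reads and may be wrong. mir-37 was read as 5' arm from 4, 1 and 2 reads of the other arm, while mir-35, mir-36 and mir-39 were read as 3' arm. At mir-57 the commonest 3' end took 54.7% of WT reads and 79.2% and 82.3% in K39A, and at mir-71 it took 52.5% in WT and 65.5% and 80.4% in K39A. At mir-58 it took 92.4% in WT and 87.1% and 80.3% in K39A, at mir-1 88.7% in WT and 85.8% and 84.6%, and at mir-44 and mir-45 87.6% in WT and 83.2% and 81.5%. Reads of the other arm took a median of 0.130% in WT, 0.122% in K39A replicate 1 and 0.0710% in K39A replicate 2. These shares have no test, and in miRNA clusters reads of a neighbour can be counted as the other arm. Read length shifted as well. mir-57 and mir-71 have modal lengths of 24 and 23 nt, and mir-58, mir-1 and mir-44 and mir-45 of 21 nt. Mean read length rose from 21.6 nt in WT to 22.1 and 22.5 in K39A at mir-71, and from 21.06 to 21.12 and 21.20 at mir-58. Changed Dicer cutting and the length difference between the libraries cannot be told apart here.

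Reads like 21U-RNAs, which do not depend on Dicer, were mostly lower in K39A relative to all reads outside ribosomal DNA. limma with voom weights called 0 of 3725 positions, with 280 at an unadjusted p under 0.05, 274 of them lower. The median log2 was -0.47, with -0.35 and -0.66 in the K39A replicates 1 and 2, and -0.56 with the miRNA size factor. In both K39A libraries 483 positions were at least 2-fold lower than WT and 109 at least 2-fold higher. With the TMM-type scaling, which sets the typical 21U position level, the median was 0.0096, with 178 lower and 271 higher. Reads of 21 nt that begin with U took 0.123% of WT reads on chromosome X and 0.0843% on chromosome V. On chromosome IV, where the 21U-RNA clusters lie, they took 11.5%.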

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

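Limma-voom counts and medians were recomputed under each setting, and the loci, the windows and the settings with no-mismatch reads or reads of 25 to 27 nt, exactly 22 nt or 21 to 23 nt were chosen after the data were seen. Of the values that answer a comparison, 112 stayed close to the main value and 39 moved. For named miRNAs, loci, windows and lists 496 stayed close, 92 moved, 17 newly passed and 5 no longer passed. Class medians counted as close within the SD of the single-library medians, whatever their sign. No called value changed sign, but uncalled medians did: those of 21U, 22G and windows under the TMM-type scaling and the median of ratios, those of 22G and 26G with a minimum of 1 read, that of the mir-51 family with reads of 21 to 23 nt, that of the mirtrons without K39A replicate 2, and that of miRNAs, near 0, with the miRNA size factor, the median of ratios and reads of 21 to 23 nt. The 22G share was higher than WT (log2 0.032) without K39A replicate 1. With single-match reads the log2 class ratio was 0.14 for miRNA and -1.52 for ribosomal fragments, and 22G loci gave 7 calls and windows 33. Against reads outside ribosomal DNA it was 0.089 for miRNA and -0.81 for other reads. Against miRNA reads it was -1.38 for ribosomal fragments, -0.55 for 21U and -0.90 for other reads. With no-mismatch reads it was -0.87 for other reads, 22G loci gave 0 calls (9 at an unadjusted p under 0.05), and windows gave 39 with a median of -0.93. A minimum of 1 read tests more features, and gave 13 calls for 21U, 22 for 22G loci and 174 for windows, with medians of -0.14, 0.47 and -0.55, and 0.092 for 26G loci. A minimum of 100 reads tests fewer, and gave 1 call for miRNAs, 0 for 22G loci (10 at an unadjusted p under 0.05) and 12 for windows, with a window median of -1.02. limma-trend gave 9 calls for 26G loci, with medians of -3.26 there and -0.68 for windows. The TMM-type scaling gave medians of 0.0096 for 21U, 0.0015 for 22G loci, 0.021 for windows and -1.66 for 26G loci, and the median of ratios 0.026 for 21U, 0.016 for 22G loci and 0.0021 for windows. Both set the typical feature of a class level by construction, apart from 26G loci. There the TMM-type scaling levelled K39A replicate 1 alone, with a median of 0.23. Replicate 2 shares no 26G-type reads with WT at any of these loci, so it stayed unscaled against WT, at -6.23. The miRNA size factor gave a window median of -0.94. Reads of 25 to 27 nt gave a 26G median of -0.50 over more loci, and exactly 22 nt left 0 calls for 22G (5 at an unadjusted p under 0.05). For the other arm of miRNAs a minimum of 1000 reads gave -0.00783 points, and leaving out 1 K39A library gave -0.00712 to 0 points. Except where the numbers tested or the construction show it, the cause was not tested. The median of ratios and the minimum of 100 reads gave no value for 26G loci. Counts of 0 allow up to 0.896, 0.591 and 0.894 RPM in the 3 libraries, which limits folds at single 26G loci. Without K39A replicate 1 or 2 the medians had no test and ranged from -6.23 to -4.63 for 26G, -0.59 to -0.31 for 22G, -0.66 to -0.35 for 21U, -0.90 to -0.82 for windows and, for miRNAs, from -0.13 without K39A replicate 1 to 0.25 without K39A replicate 2, which differ in sign. No paired analysis was possible because no label pairs a WT with a K39A library.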

Other observations

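Among the tests in this part, that of read length for miRNAs was chosen before its result was seen, and those of size selection, shifted or shorter ends, embryo number, mismatched reads, multiple matches, random fragments and duplex geometry were chosen after.

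The X chromosome locus from 9071753 to 9073222 held small RNA of many lengths on its minus strand. All lengths together gave 773 reads in WT, 1 in K39A replicate 1 and 1 in K39A replicate 2, with reads of several matches split. Single-match reads numbered 191, 1 and 1 in the same order. Most WT reads counted there were thus shares of reads with several matches. Reads of 18 nt (256 in WT) and 19 nt (217) outnumbered those of 22 nt (64.9), and the opposite strand held 5, 0 and 0 reads. A further pair of 22G-type loci, chosen after their values were seen, held similar levels in both K39A libraries and another level in WT, and neither passed the test with a minimum of 20 reads and all matches. On chromosome II from 15165818 to 15165881, minus strand, there were 117 reads in WT, 26 in K39A replicate 1 and 18 in K39A replicate 2 (limma adjusted p = 0.0701), and the locus passed in 2 of 8 settings, with single-match reads and with a minimum of 1 read, over a range of adjusted p from 4.71e-05 to 0.761. On chromosome III from 9240650 to 9242215, minus strand, there were 4, 37 and 23 in the same order (limma adjusted p = 0.791, from 0.433 to 0.989 over 7 settings).

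The scarcity of 26G-type reads in both K39A libraries was first set against selection of shorter RNA on the gel, which would lower all 26-nt reads, but those with another first base than G, outside miRNA hairpins and ribosomal DNA, had a log2 ratio of 3.01. Ends shifted by 1 nt are argued against at the 9 loci, where reads of 25 and 27 nt that begin with G, which did not pick the loci, had a log2 ratio of -5.21. At the locus on chromosome II from 3291529 to 3291778, reads of 24 and 25 nt that begin with G gained 69.8% of the RPM that 26-nt reads lost. The gain was 87.6% and 57.3% in the K39A replicates 1 and 2, and the log2 ratio of these reads was 1.34. Longer reads were commoner across both K39A libraries, with ratios of similar or larger size given next for 25 and 27 nt. Shorter ends and this length difference thus cannot be told apart at that locus. Outside the 11 loci a shift stays open, since reads of 25 and 27 nt with G had a log2 ratio of 1.15 there. Reads of these lengths with other first bases, counted inside the loci as well, had 2.16. Fewer embryos and oocytes would lower the mir-35 family about as far, and its median log2 was -0.34 (-0.52 and -0.23 in the single libraries), whereas sperm number, which the list does not mark, and a need for the Dicer helicase domain stay open and were not tested.

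Differences of miRNA level between the libraries could come from read-length selection, since K39A had fewer reads of 18 to 20 nt. Modal length explained 27.5% of the variance of the log2 change over 99 miRNAs, between the bounds of 25% and 50% set beforehand, with 32.8% in K39A replicate 1 and 15.2% in K39A replicate 2. The median log2 change was -0.49 for the 13 miRNAs of 21 nt and 0.94 for the 15 of 24 nt. Length and genotype cannot be told apart for that part, because all WT reads come from 1 library. Mismatched reads as the source are argued against, since leaving them out lowered the SD over miRNAs in K39A replicate 2 by 0.116%.

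The reads at the X chromosome locus in WT alone were weighed against 2 explanations. Reads that match several places are argued against as the only source, since 99.1% of the single-match RPM lay in WT. The larger part of the WT reads there matched several places, and where those came from stays open. Random fragments of an RNA present in WT stay open. Of 146 single-match reads of 18 to 20 nt, which did not pick the locus, 14.4% began with G (95% exact interval 9.13 to 21.1). That lay below the 24.4% of other such WT reads. Reads of 21, 22 and 23 nt went the other way. They numbered 109, 64.9 and 15.5 in WT over all matches, and 155 of them began with G. Reads with G at these lengths picked the locus, so their excess cannot decide the question. A difference between the strains or arrays other than the K39A change stays open, as does the K39A change itself, and neither was tested.

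As a hypothesis, 26G-type reads and the shorter reads opposite to them may come from duplexes of fixed geometry. In WT the 9 loci held 94 distinct starts of 26G-type reads and 199 distinct 3' ends of opposite reads of 18 to 23 nt, of which 19 nt was the commonest length, at 42.5% of reads. The 3' ends gathered 5 nt inside the 26G start, with 15 pairs, and at 4 nt with 13 and 3 nt with 9, and the commonest distance held 4.73 times the mean. Random shifts of the starts by up to 25 nt reached 15 pairs at any distance with a permutation p of 0.0002 (1-sided, 10000 shifts). Each start was shifted on its own, which removes any clustering of neighbouring starts, so this p may be too small. Neighbouring starts and ends also count as separate pairs, so pairs at 3, 4 and 5 nt need not be independent.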
